A study of Homo sapiens with 6 samples.

How the data were processed

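Gene expression was measured by RNA sequencing in 6 libraries labelled as A498 cells, 3 with a control shRNA and 3 with an shRNA against RNF26. Per the labels' protocols, the cells were grown in RPMI-1640 with fetal bovine serum, RNA was extracted with an RNeasy kit, and libraries were made with a NEBNext directional kit, which marks strand. Groups and replicate numbers were taken from the sample titles.

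The authors deposited 1 table of the whole series with 61541 Ensembl genes in rows and the 6 libraries in columns. Although the table is named for FPKM, the deposited values are raw gene counts: they are whole numbers throughout, with totals that differ between libraries. They were therefore treated as counts. Genome build hg19 is given in the submitters' processing notes. The aligner, the counting program, the annotation release, the strand setting and any handling of reads that match several genes are not given in the sources used here. Without a strand setting, genes that overlap on opposite strands cannot be separated with certainty, and genes with near-identical copies can lose or share reads. The table also had 2 blank rows, which named no gene, held 0% of the counts and were left out. Symbols came from a table of gene names for 61369 of the IDs, and from GENCODE 29 for another 105. GENCODE 29 also gave the overlapping neighbours of the named genes, without coordinates, because its build is not the one in the processing notes. Such overlaps are stated below for some of the named genes only, so a gene without a stated overlap may still have one.

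Totals per library were 18021718, 16923786 and 16915790 counts in the control group and 17202935, 17824141 and 16682871 in the knockdown group. At that depth 1 count is worth 0.0555 to 0.0599 CPM, and a count of 0 allows up to 3 counts, or 0.166 to 0.180 CPM. This floor covers counting error alone. Libraries of the same group correlated at 0.9948 to 0.9961 across genes (log2 CPM), and libraries of different groups at 0.983 to 0.985. Genes are not independent replicates. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.31 to 4.98 for pairs within a group, so all 6 libraries were counted as separate samples.

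The comparison fixed before the data were examined assumed FPKM and a limma test, with edgeR in its place if the table held counts. Since it held counts, the main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with trimmed mean of M values (TMM) scaling. TMM factors were 0.966 to 0.971 in the control libraries and 1.031 to 1.033 in the knockdown libraries. The planned minimum of mean FPKM 1 became a mean of at least 1 CPM over the 6 libraries, which kept 14766 genes holding 99.7% of the counts. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05, and standard errors were taken as the absolute log2 fold change over the square root of the F statistic. The biological coefficient of variation was 0.0507. Levels are TMM-scaled CPM as mean ± SD unless named as CPM of total counts.

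The 34 gene lists were fixed before the data were examined, and lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2(CPM + 1), with a preset correlation of 0.01 between genes. The alternative estimated that correlation from the data. The p-values were adjusted over the 30 tested lists. Genes were named by a rule fixed at the same time. RNF26, TSC1, TSC2, CDK4, CDK6, VEGFA and STING1 were always named. The 12 largest rises and the 12 largest falls among called genes whose groups did not overlap followed, leaving out short RNAs and genes without a symbol. From each list up to 4 called members with the largest change were named, or 2 members by smallest p where none was called. A few genes that this rule selects or the lineage figure would show are not reported here.

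On simulated counts for the 14766 genes, drawn from the means and library sizes of this comparison with 50 genes changed at each fold, the test recovered 52% of genes changed 1.25-fold, 74% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. Of 174 calls 15 were false, or 8.62%, above the nominal 5%. This was a single draw, with far fewer changed genes than the 6117 called in the data. The shares recovered and false therefore need not hold for the real comparison. Camera called 0 of 30 lists in the simulated counts, in which genes were drawn independently. With the preset correlation it called 6 to 12 lists in other splits of the real libraries. Those splits mix libraries of both groups and keep part of the group difference, so this is not a rate of false calls.

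Other settings chosen in advance were fits on log2(CPM + 0.1) and log2(CPM + 0.01), 3 other filters on low counts, other scalings, other variance models, the replicate number as a block, an estimated correlation for the lists and leaving out each of the 6 libraries. A rescaling of FPKM to a common total per library, chosen in advance, was run as scaling by total counts, without gene lengths. DESeq2 1.42.0, the filterByExpr filter, limma with a trend on log2(CPM + 1) and removal of a trend on transcript length and GC content were added after seeing the data. Length and GC were available for 98.8% of the tested genes.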

Results

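RNA sequencing was used to ask which transcripts change when RNF26 is knocked down in cells labelled A498. That line derives from a human clear cell renal carcinoma. The identity of the cells rests on the labels. Of 24 renal and clear cell carcinoma markers, 15 had a mean below 1 CPM, as given below. RNF26 is an E3 ubiquitin ligase anchored in the endoplasmic reticulum membrane. The series title places the experiment in a study of CDK4/6 inhibitors, RNF26, the stability of TSC1 and the response of clear cell renal carcinoma to anti-angiogenic drugs. The libraries formed 2 groups of 3, cells with a control short hairpin RNA (shRNA) and cells with an shRNA against RNF26. Each library held between 16682871 and 18021718 gene counts. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

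RNF26 (ENSG00000173456) fell in the knockdown libraries from 1972 ± 49.7 CPM (gene counts scaled to library size) to 68.7 ± 0.482 CPM (mean ± SD, n = 3 per group), which left 3.48% of the control level. The counts in the control libraries were 35331, 31901 and 31928, against 1216, 1274 and 1175 in the knockdown libraries. The log2 fold change was -4.84 (SE 0.040, edgeR quasi-likelihood adjusted p = 4.27e-24). RNF26 ranked 15 to 16 among all genes by count in the control libraries and 3725 to 3776 in the knockdown libraries. Gene counts do not tell transcripts of the chromosomal gene from transcripts of an introduced copy.

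**Figure D1:**
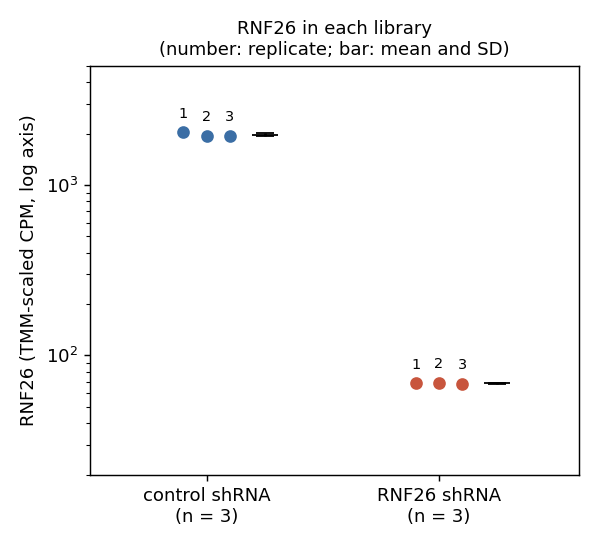
RNF26 level in each of the 6 libraries, as CPM scaled by the trimmed mean of M values, on a log axis. Numbered points are replicates and the bar beside each group is its mean with the SD. The control libraries averaged 1972 CPM and the knockdown libraries 68.7 CPM.

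Beyond RNF26, the broadest falls in the knockdown libraries were in immediate early genes, replication-dependent histone genes, interferon-stimulated genes, secreted angiogenesis regulators, unfolded protein response genes, ATF4 target genes and YAP/TEAD target genes. These 7 lists were called lower both with the preset correlation and with an estimated correlation between genes. Of the 34 lists fixed in advance, 30 had enough measured members to be tested, and 18 were called with the preset correlation, 16 lower and 2 higher. Other splits of the 6 libraries into 3 and 3 called 6 to 12 lists with the preset correlation and 0 with an estimated correlation. Each of those splits mixed libraries of both groups, so neither number gives a rate of false calls for the lists called here. Across 14766 tested genes, 6117 changed at an adjusted p below 0.05 in the edgeR quasi-likelihood test, 2785 higher and 3332 lower. With libraries scaled by total counts alone the split turned to 4449 higher and 2269 lower, so the direction of small changes depended on the scaling. Changes of at least 2-fold were found for 434 genes, 80 higher and 354 lower, and changes of at least 4-fold for 6 higher and 83 lower. The count of 434 depended on the filter and the offset, with 815 without a filter on low counts, 782 at a minimum mean of 0.1 CPM, 224 at a minimum mean of 5 CPM, 277 with limma on log2(CPM + 1) and 269 with that fit without a trend.

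**Figure D2:**
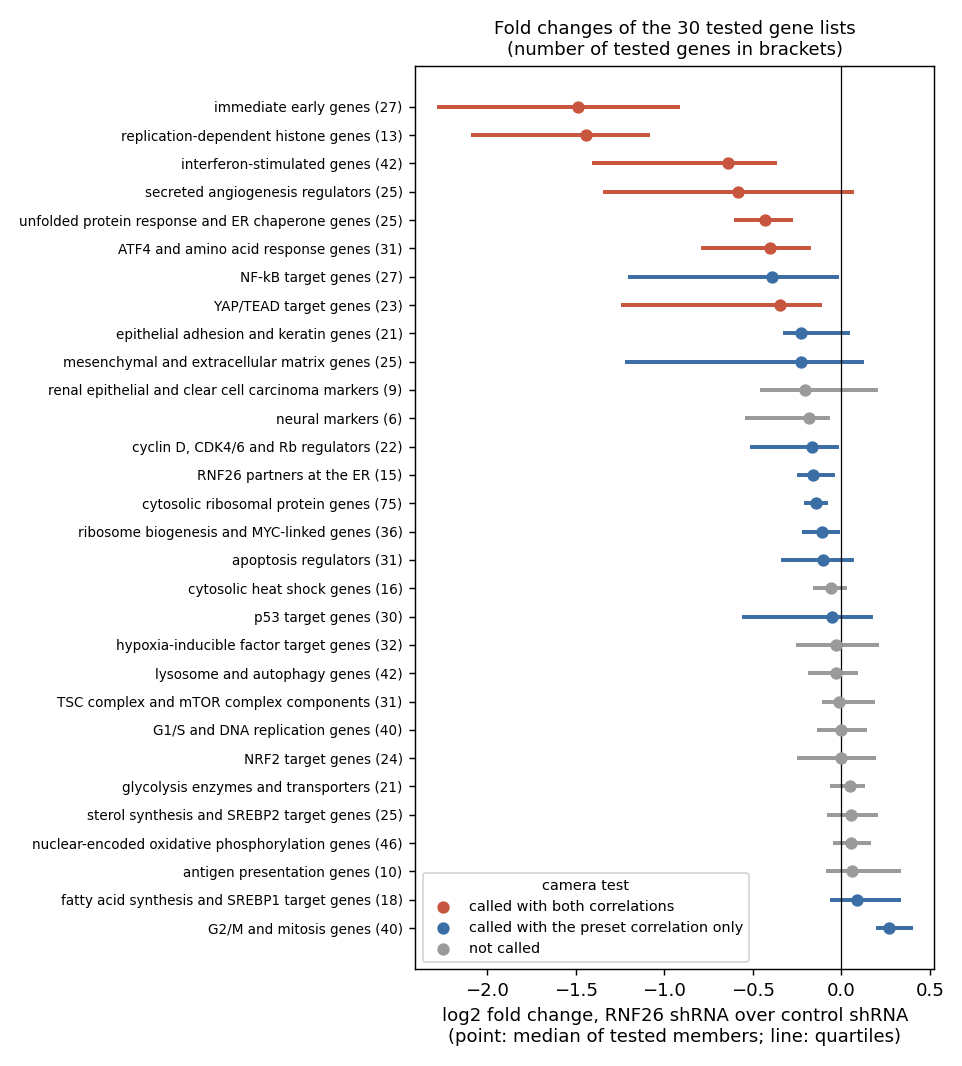
Median log2 fold change (point) and quartiles (line) of the tested members of each of 30 gene lists, RNF26 shRNA over control shRNA, with colours for the camera test. The immediate early genes (median -1.49) and the histone genes (median -1.44) lie lowest, and the G2/M genes (median 0.27) lie highest.

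Among the 12 largest falls were S1PR1, a sphingosine 1-phosphate receptor, the cytokine IL6, the secreted matricellular protein CCN1 and the cornified envelope genes SPRR2A and SPRR2D. CCN1 was the most abundant of them and fell from 345 ± 19.0 to 29.2 ± 1.40 CPM, or 11.8-fold (log2 fold change -3.56, SE 0.055). S1PR1 was 15.9-fold lower, IL6 13.1-fold lower, SPRR2A 18.9-fold lower and SPRR2D 11.9-fold lower. Others rested on few counts in the knockdown libraries. The pseudogene KLKP1 had 128, 194 and 230 counts in the control libraries and 1, 1 and 0 in the knockdown libraries. The interferon-stimulated gene IFI27 had 79, 79 and 76 counts against 0, 4 and 1, and its log2 fold change of -5.53 became -7.02 without knockdown replicate 2. The histone gene H2AC12 had 58, 50 and 47 counts against 1, 3 and 2, the histone gene H1-4 had 62, 48 and 36 against 4, 2 and 7, and GOLGA6C had 44, 31 and 46 against 3, 3 and 0. DUSP8 and BCYRN1 were each driven by 1 control library. DUSP8 had 107 of its counts in control replicate 2, without which its log2 fold change moved from -4.54 to -2.99, and BCYRN1 had 281 in control replicate 3, without which it moved from -3.69 to -1.42. Without knockdown replicate 2 the value of BCYRN1 was -4.35. A robust edgeR fit ended the calls of DUSP8 (adjusted p = 0.092) and BCYRN1 (adjusted p = 0.15). SPRR2A, SPRR2D, H2AC12, H1-4, GOLGA6C and BCYRN1 have near-identical relatives, and their counts are uncertain where reads were shared.

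The 12 largest rises were smaller than the largest falls and were mostly in genes with low counts. MPPED2 was the most abundant of them and rose from 23.3 ± 0.595 to 77.6 ± 1.08 CPM, or 3.33-fold (log2 fold change 1.74, SE 0.058, edgeR adjusted p = 1.13e-14). The angiogenic ligand ANGPT1 rose 3.06-fold, from 3.04 ± 0.632 to 9.32 ± 0.468 CPM. AKR1C2, an aldo-keto reductase, rose 2.94-fold to 16.5 ± 1.76 CPM, and the alcohol dehydrogenase ADH1C rose 2.80-fold to 6.90 ± 0.524 CPM. The serpin genes SERPINB3 and SERPINB13 rose 2.96-fold and 3.14-fold, and the Wnt ligand WNT10A rose 4.03-fold to 4.35 ± 0.558 CPM. GTF2H2C rose 5.10-fold, SAMD11 3.89-fold, SNCAIP 3.16-fold, CYP26A1 3.04-fold and EXOC3L4 3.01-fold, each from below 1 CPM in the control libraries. GTF2H2C, AKR1C2, ADH1C and SERPINB3 have near-identical relatives, and SAMD11 and SNCAIP overlap genes on the opposite strand, so these counts are uncertain.

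TSC1, the gene whose protein the series title names, had 95.1 ± 4.36 CPM in the control libraries and 93.7 ± 3.61 CPM in the knockdown libraries. Its log2 fold change was -0.02 (SE 0.051, edgeR adjusted p = 0.76), and scaling by total counts gave 0.07. TSC2, its partner in the complex that restrains mTORC1, rose from 77.0 ± 2.87 to 96.7 ± 3.69 CPM (log2 fold change 0.33, SE 0.051, edgeR adjusted p = 3.6e-05). TSC2 overlaps PKD1 and NTHL1 on the opposite strand, and how the counting treated strand is not given in the sources used here. Over the 31 tested components of the TSC and mTOR complexes, 10 rose, 4 fell and 17 did not pass. Adjusted over the list alone, 10 rose and 5 fell. The 4 that fell were RRAGC (-0.72) and RHEB (-0.46), GTPases that act in mTORC1 activation, the translation repressor EIF4EBP1 (-0.43) and the PI3-kinase subunit PIK3CA (-0.27), on the log2 scale. MLST8, a subunit of both mTOR complexes, rose by 0.43 on that scale. As a list these genes were not called (camera adjusted p = 0.50), and the camera direction was up while the median (-0.01) and the mean (-0.00075) lay just below 0. The sign of the median depended on the setting, from -0.03 without control replicate 1 to 0.08 with total-count scaling and 0.10 with quantile normalization. Gene counts measure transcripts, not the amount or stability of a protein.

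Immediate early genes, which are transcribed within minutes of a growth factor or stress signal, fell together. Of 27 tested, 25 fell, 0 rose, and FOSL2 and BTG2 did not pass (log2 fold change -0.02 and 0.07), with the same counts adjusted over the list alone. JUN, a subunit of the AP-1 transcription factor, fell from 967 ± 71.1 to 146 ± 6.09 CPM (log2 fold change -2.73, SE 0.051), and the stress-induced factor ATF3 from 64.1 ± 2.29 to 9.40 ± 0.886 CPM (-2.77, SE 0.078). ZFP36, which promotes decay of cytokine transcripts, was 6.63-fold lower. The list median was -1.49 (camera adjusted p = 4.5e-26, and adjusted p = 0.014 with an estimated correlation). YAP/TEAD target genes moved the same way, with 17 of 23 lower, 1 higher (ARHGEF17, 0.39) and 5 not passing, or 18 lower and 2 higher adjusted over the list alone. Their median was -0.35 (camera adjusted p = 5.5e-10, and adjusted p = 0.022 with an estimated correlation). CCN1, which belongs to both lists, CCN2 (3.55-fold lower), ANKRD1 (5.65-fold lower) and GADD45B (7.18-fold lower) had the largest changes, and YAP1 itself had a log2 fold change of 0.05 that did not pass.

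Replication-dependent histone genes were lower in the knockdown libraries, at low levels in both groups. Of 13 tested, 12 fell, 0 rose and H2AC20 did not pass (log2 fold change -0.06), with the same counts adjusted over the list alone. The median was -1.44 (camera adjusted p = 1.8e-07, and adjusted p = 0.022 with an estimated correlation). H2BC8 fell from 7.15 ± 0.707 to 0.766 ± 0.116 CPM, H4C5 from 4.03 ± 0.465 to 0.471 ± 0.237 CPM and H2AC8 from 2.17 ± 0.164 to 0.506 ± 0.196 CPM. Most of these transcripts end in a stem-loop instead of a poly(A) tail, and SLBP, which encodes the protein that binds this stem-loop, fell from 114 ± 4.56 to 68.7 ± 0.891 CPM. Paralogous histone genes can share reads, so the values of single members are uncertain.

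Unfolded protein response and endoplasmic reticulum chaperone genes were lower. Of 25 tested, 24 fell, 0 rose and the sensor ATF6 did not pass (log2 fold change 0.06), with the same counts adjusted over the list alone. HSPA5, the most abundant of the named members and the main chaperone of the endoplasmic reticulum, fell from 3306 ± 89.6 to 1394 ± 4.11 CPM (log2 fold change -1.25, SE 0.031). HERPUD1, a component of endoplasmic reticulum associated degradation, was 5.56-fold lower, the co-chaperone DNAJB9 4.32-fold lower and HYOU1 1.61-fold lower. DNAJB9 and HYOU1 overlap genes on the opposite strand. The list median was -0.43 (camera adjusted p = 8.5e-15, and adjusted p = 0.014 with an estimated correlation). ATF4 and amino acid response genes moved the same way, with 23 of 31 lower, 1 higher (the amino acid transporter SLC7A1, 0.29) and 7 not passing, or 25 lower and 1 higher adjusted over the list alone. DDIT3, which encodes the transcription factor CHOP, was 3.92-fold lower, STC2 2.55-fold lower and CHAC1 2.51-fold lower. DDIT3 overlaps MARS on the opposite strand. This list had a median of -0.41 (camera adjusted p = 9.6e-11, and adjusted p = 0.014 with an estimated correlation).

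Genes for proteins described with RNF26 at the endoplasmic reticulum were partly lower. Of 15 tested, 8 fell, 0 rose and 7 did not pass, with the same counts adjusted over the list alone. The median was -0.16 (camera adjusted p = 0.025, but adjusted p = 0.18 with an estimated correlation), and scaling by total counts ended the call (median -0.07, camera adjusted p = 0.056). The ubiquitin-conjugating enzyme UBE2J1 had a log2 fold change of -0.40 (SE 0.064), the DNA sensor CGAS -0.39 (SE 0.056) and the autophagy receptor TAX1BP1 -0.30 (SE 0.052). EPS15 had -0.25, a call lost with total-count scaling (-0.16) and with limma on log2(CPM + 1) without a trend (-0.24). The call was also lost without control replicate 2 (-0.22), knockdown replicate 1 (-0.22) or knockdown replicate 2 (-0.19). STING1, a reported substrate of RNF26, was near the lowest level tested, at 2.33 ± 0.214 CPM in the control libraries and 2.29 ± 0.183 CPM in the knockdown libraries (log2 fold change -0.03, SE 0.22, edgeR adjusted p = 0.94).

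Secreted angiogenesis regulators were mostly lower. VEGFA, the principal endothelial growth factor and the ligand blocked by several anti-angiogenic drugs, fell from 232 ± 7.06 to 121 ± 3.87 CPM (log2 fold change -0.94, SE 0.043, edgeR adjusted p = 1.75e-12). Of 25 tested regulators, 18 fell, 3 rose and 4 did not pass, with the same counts adjusted over the list alone, and the median was -0.58 (camera adjusted p = 3.0e-09, and adjusted p = 0.014 with an estimated correlation). ANGPTL4 was 6.72-fold lower and the vasoconstrictor peptide gene EDN1 4.56-fold lower. IL6 and CCN1, given above, also belong to this list. The list holds stimulators and inhibitors of angiogenesis together, so its call gives no net direction for angiogenesis. The inhibitor THBS1 was among the members that fell, from 835 ± 10.0 to 332 ± 7.94 CPM. The 3 that rose were ANGPT1 (1.61), COL18A1 (0.37) and PDGFC (0.15), on the log2 scale. VEGFA overlaps a non-coding gene on the opposite strand.

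Hypoxia-inducible factor targets went both ways. Of 32 tested, 9 rose, 10 fell and 13 did not pass, or 11 higher and 10 lower adjusted over the list alone, and the list was not called (median -0.03, camera adjusted p = 0.23). The sign of the median depended on the setting, from -0.06 without a filter on low counts to 0.06 with total-count scaling. Among the members that fell most were ANGPTL4, ADM (3.56-fold lower) and CCND1 (2.25-fold lower), which are also targets of other stress and growth signals. The 21 tested genes of glycolysis were not called either (5 higher, 1 lower, median 0.05, camera adjusted p = 0.27). Adjusted over the list alone, 3 of them were higher and 1 lower. They became called higher with total-count scaling (median 0.14, camera adjusted p = 0.046) and with quantile normalization (median 0.17, camera adjusted p = 0.0027). PFKL rose 1.28-fold, and the lactate transporter SLC16A1 had a log2 fold change of -0.21, a call lost with quantile normalization. ALDOC had a log2 fold change of 0.93, a call lost without control replicate 1 (0.78) or knockdown replicate 2 (0.64).

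Interferon-stimulated genes were lower. Of 42 tested, 34 fell, 1 rose (IRF1, 0.21 on the log2 scale) and 7 did not pass, or 36 lower and 1 higher adjusted over the list alone. IFI6 fell from 67.6 ± 3.85 to 10.2 ± 1.35 CPM (log2 fold change -2.73, SE 0.084). BST2, a surface protein that tethers budding viruses, was 5.93-fold lower at 1.92 ± 0.448 CPM in the control libraries. The transcription factor IRF7 was 6.73-fold lower, with control counts of 104, 40 and 174 and knockdown counts of 16, 22 and 12. The median was -0.64 (camera adjusted p = 2.3e-14, and adjusted p = 0.014 with an estimated correlation). Antigen presentation genes were not called, with 3 of 10 higher, 0 lower and the same counts adjusted over the list alone (median 0.06, camera adjusted p = 0.17). Their median turned to -0.07 without a filter on low counts and was 0.20 with a minimum mean of 5 CPM, 0.15 with total-count scaling and 0.13 with quantile normalization, and leaving out 1 library gave 0.04 to 0.14. The 3 were CIITA (0.53), the peptidase ERAP2 (0.41) and the proteasome subunit PSMB10 (0.37), on the log2 scale. The call for PSMB10 was lost without control replicate 2 (0.24), knockdown replicate 1 (0.37) or knockdown replicate 2 (0.33).

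NF-kB targets included some of the larger falls in cytokine genes. CSF2, a myeloid growth factor, fell from 87.1 ± 9.70 to 8.51 ± 0.752 CPM (10.2-fold), the chemokine CXCL2 from 210 ± 13.7 to 59.2 ± 4.35 CPM (3.55-fold) and the chemokine CCL20 was 2.47-fold lower. Of 27 tested, 17 fell, 5 rose and 5 did not pass, or 19 lower and 5 higher adjusted over the list alone. The 5 that rose were TNFAIP2 (0.83), SOD2 (0.39), REL (0.26), the inhibitor NFKBIA (0.24) and TNIP1 (0.15), on the log2 scale. The list had a median of -0.39 (camera adjusted p = 3.3e-06, but adjusted p = 0.072 with an estimated correlation).

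G2/M and mitosis genes were slightly higher. Of 40 tested, 35 rose, 0 fell and 5 did not pass, with the same counts adjusted over the list alone, and the median was 0.27 (camera adjusted p = 1.5e-13, but adjusted p = 0.15 with an estimated correlation). The mitotic kinesin KIF20A rose from 54.2 ± 1.23 to 89.8 ± 5.89 CPM (1.66-fold), HMMR 1.58-fold, CDK1 1.44-fold and the topoisomerase TOP2A 1.43-fold. KIF20A and HMMR overlap genes on the opposite strand. G1/S and DNA replication genes were not called, with 11 higher, 10 lower and 19 not passing of 40, or 12 higher and 11 lower adjusted over the list alone (camera adjusted p = 0.97). Their camera direction was up while the median (-0.00091) and the mean (-0.014) lay just below 0, and the median was 0.09 with total-count scaling or quantile normalization. CDC25A, a phosphatase that activates cyclin-dependent kinases, was 1.70-fold lower, and POLA2 and LIG1 rose 1.35-fold and 1.32-fold.

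CDK4 and CDK6, the targets of the inhibitors in the series title, were both expressed. CDK4 had 125 ± 6.33 CPM in the control libraries and 126 ± 4.97 CPM in the knockdown libraries (log2 fold change 0.02, SE 0.049, edgeR adjusted p = 0.84). CDK6 fell from 271 ± 12.4 to 186 ± 8.89 CPM (log2 fold change -0.54, SE 0.046, edgeR adjusted p = 1.77e-08). The difference between the changes of these genes was not tested. Over 22 tested cyclin D, CDK4/6 and Rb regulators, 11 fell, 3 rose and 8 did not pass, with the same counts adjusted over the list alone (median -0.16, camera adjusted p = 0.0019, but adjusted p = 0.069 with an estimated correlation). With total-count scaling and with quantile normalization the median was -0.07. CCND1, which encodes cyclin D1, fell from 512 ± 2.40 to 228 ± 4.52 CPM. The inhibitors of cyclin-dependent kinases CDKN2B and CDKN1A were also lower, by 2.57-fold and 1.82-fold, so the members that fell included genes that promote and genes that restrain the G1/S transition. The 3 that rose were E2F2 (0.90), the inhibitor gene CDKN2C (0.65) and RBL2 (0.39), on the log2 scale. CDK4, CCND1 and CDKN1A overlap genes on the opposite strand.

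Fatty acid synthesis genes were partly higher. SREBF1, which encodes the transcription factor SREBP1, rose from 77.8 ± 5.39 to 130 ± 2.71 CPM, the desaturase SCD from 390 ± 13.2 to 588 ± 16.7 CPM and FASN, the fatty acid synthase, from 894 ± 43.4 to 1227 ± 5.09 CPM. Of 18 tested, 7 rose, 2 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.09, camera adjusted p = 0.0091, but adjusted p = 0.15 with an estimated correlation). The median was 0.06 without control replicate 2, 0.05 without knockdown replicate 3 and 0.18 with total-count scaling. The 2 that fell were AGPAT2 (-0.30) and ACACA (-0.93), on the log2 scale. The value of ACACA rested on 285 counts in control replicate 2, without which it was -0.05, and its call was also lost without knockdown replicate 1 (-0.93), 2 (-0.95) or 3 (-0.90). Sterol synthesis genes were not called, with 9 of 25 higher, 4 lower and the same counts adjusted over the list alone (median 0.05, camera adjusted p = 0.11). They became called higher with total-count scaling (median 0.14, camera adjusted p = 0.045) and without a filter on low counts (camera adjusted p = 0.038), and the median was 0.09 without control replicate 2, with quantile normalization and with a length and GC trend removed. MVK rose 1.42-fold and CYP51A1 was 1.41-fold lower.

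Ribosomal protein genes were slightly lower. Of 75 tested, 44 fell, 0 rose and 31 did not pass, or 47 lower and 1 higher adjusted over the list alone. The median was -0.14 (camera adjusted p = 2.3e-07, but adjusted p = 0.20 with an estimated correlation), and quantile normalization ended the call (median -0.01, camera adjusted p = 0.72), while total-count scaling gave a median of -0.05. RPL12 fell from 673 ± 27.3 to 531 ± 13.6 CPM and RPS15A from 90.1 ± 5.68 to 72.1 ± 2.87 CPM, RPL30 was 1.22-fold lower and RPL28 1.22-fold lower. Ribosomal protein genes have many pseudogenes that can share their reads. Ribosome biogenesis and MYC-linked genes had 14 of 36 lower, 4 higher and 18 not passing, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.0075, but adjusted p = 0.075 with an estimated correlation). Quantile normalization ended this call too (median -0.06, camera adjusted p = 0.054), and total-count scaling gave a median of -0.02. The transcription factor gene MYC fell from 418 ± 28.0 to 168 ± 6.69 CPM (log2 fold change -1.32, SE 0.048), and LYAR and GAR1 were 1.41-fold and 1.38-fold lower. RRN3 had a log2 fold change of -1.20 at 1.83 ± 1.20 CPM in the control libraries, a call lost without control replicate 2 (-0.55) or knockdown replicate 1 (-0.93). The nuclear-encoded genes of oxidative phosphorylation were not called, with 12 of 46 higher, 2 lower (CYCS, -0.37, and NDUFA4, -0.17) and the same counts adjusted over the list alone (median 0.05, camera adjusted p = 0.090). They became called higher with total-count scaling (median 0.14, camera adjusted p = 0.014), without a filter on low counts (camera adjusted p = 0.021), with quantile normalization (median 0.11, camera adjusted p = 0.014), with a length and GC trend removed (median 0.08, camera adjusted p = 0.019), and without control replicate 3 (camera adjusted p = 0.036) or knockdown replicate 3 (median 0.08, camera adjusted p = 0.040). Without control replicate 1 the median was 0.03 (camera adjusted p = 0.21). SDHC rose 1.17-fold. NDUFS7 had a log2 fold change of 0.27, a call lost without control replicate 3 (0.19).

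Stress and cell death genes were led by falls in individual members. GADD45A, a growth arrest gene, fell from 352 ± 26.3 to 51.8 ± 6.47 CPM (6.79-fold), PMAIP1, which encodes the pro-apoptotic protein NOXA, was 2.77-fold lower, SESN2 2.33-fold lower, PLK2 2.02-fold lower and PLK3 1.85-fold lower. Of 30 p53 target genes, 11 fell, 7 rose and 12 did not pass, or 12 lower and 8 higher adjusted over the list alone (camera adjusted p = 0.041, but adjusted p = 0.17 with an estimated correlation). Their median was -0.05 and turned to 0.04 with total-count scaling, with -0.10 without control replicate 3 and -0.09 without knockdown replicate 1. The call was lost without control replicate 1 (camera adjusted p = 0.055), with a minimum mean of 5 CPM (camera adjusted p = 0.056), with limma on log2(CPM + 1) without a trend (camera adjusted p = 0.080) and with a length and GC trend removed (median -0.02, camera adjusted p = 0.0504). Of 31 apoptosis regulators, 12 fell, 5 rose and 14 did not pass, or 15 lower and 6 higher adjusted over the list alone (median -0.10, camera adjusted p = 0.032, but adjusted p = 0.17 with an estimated correlation), a call lost without control replicate 3 (camera adjusted p = 0.051), with a minimum mean of 5 CPM (camera adjusted p = 0.051) and with limma on log2(CPM + 1) without a trend (camera adjusted p = 0.059). The median was -0.01 with total-count scaling and -0.03 with quantile normalization. The death receptor gene TNFRSF10A was 1.83-fold lower and BBC3 1.73-fold lower, and the pro-apoptotic gene BMF rose 1.72-fold. Cytosolic heat shock genes were not called, with 6 of 16 lower and 2 higher, or 7 lower and 2 higher adjusted over the list alone (median -0.06, and 0.03 with total-count scaling and 0.09 with quantile normalization, camera adjusted p = 0.098). They became called lower without control replicate 3 (median -0.09, camera adjusted p = 0.044), without a filter on low counts (camera adjusted p = 0.047) and with a minimum mean of 0.1 CPM (camera adjusted p = 0.049). The co-chaperone gene DNAJB1 had a log2 fold change of -0.68, BAG3 was 1.44-fold lower and CHORDC1 1.20-fold lower. HSPA4L had a log2 fold change of 0.23, a call lost without control replicate 1 (0.17) or knockdown replicate 3 (0.15).

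Lysosome and autophagy genes regulated by TFEB and TFE3 were not called, with 9 of 42 lower, 5 higher and 28 not passing, and the same counts adjusted over the list alone (median -0.03, but -0.05 without knockdown replicate 3, 0.00043 with quantile normalization and 0.06 with total-count scaling, camera adjusted p = 0.57). MAP1LC3B, which encodes an autophagosome protein, fell from 120 ± 4.47 to 60.0 ± 1.09 CPM, and the protease genes CTSL and CTSD went apart, CTSL 1.57-fold lower and CTSD 1.52-fold higher. NRF2 targets were not called, with 9 of 24 lower and 6 higher, or 9 lower and 7 higher adjusted over the list alone (camera adjusted p = 0.99). Their camera direction was up while the median (-0.00088) and the mean (-0.00047) lay just below 0, and the median ran from -0.05 without knockdown replicate 3 to 0.09 with total-count scaling. TXNRD1, which encodes a thioredoxin reductase, was 1.76-fold lower, the cystine transporter SLC7A11 1.64-fold lower and SRXN1 1.58-fold lower, against the rise of AKR1C2.

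Mesenchymal and epithelial genes both had more members lower than higher. SNAI2, a repressor of epithelial genes, fell from 312 ± 13.1 to 70.3 ± 3.33 CPM, the intermediate filament gene VIM from 49.9 ± 1.01 to 19.3 ± 1.38 CPM, and SNAI1 was 4.79-fold lower at 3.08 ± 0.178 CPM in the control libraries. Of 25 tested mesenchymal and matrix genes, 14 fell, 5 rose and 6 did not pass, or 14 lower and 6 higher adjusted over the list alone (median -0.23, camera adjusted p = 0.0016, but adjusted p = 0.069 with an estimated correlation, and median -0.14 with total-count scaling or quantile normalization). The 5 that rose were LOX (0.36), TNC (0.31), FN1 (0.15), MMP2 (0.15) and COL4A2 (0.09), on the log2 scale. Of 21 epithelial genes, 12 fell, 1 rose (GRHL2, 0.18) and 8 did not pass, or 12 lower and 2 higher adjusted over the list alone (median -0.23, camera adjusted p = 0.0048, but adjusted p = 0.17 with an estimated correlation). Quantile normalization ended this call (median -0.11, camera adjusted p = 0.14), and the median lay between -0.14 and -0.13 without control replicate 1 or knockdown replicate 2, with total-count scaling, no filter, a minimum mean of 0.1 CPM, filterByExpr, library weights or limma on log2(CPM + 1). KRT18 was 1.49-fold lower, CRB3 1.48-fold lower, and the claudin genes CLDN1 and CLDN4 1.46-fold and 1.44-fold lower. KRT18, CRB3 and VIM overlap genes on the opposite strand.

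Genes that mark renal epithelium and clear cell carcinoma were mostly near the floor in both groups. Of the 24 listed, 15 had a mean below 1 CPM over the 6 libraries. EMX2 and HAVCR1 had 0 counts in every library, which allows up to 0.166 to 0.180 CPM per library, and PAX2 had 7 counts over all libraries. PAX8 had 2.81 ± 0.344 CPM in the control libraries and 2.19 ± 0.275 CPM in the knockdown libraries, and CA9 had 0.133 ± 0.0824 and 0.688 ± 0.392 CPM, both genes as CPM of total counts. EPAS1, VHL, MME, MET, EGFR and AXL were above 10 CPM, and of the 9 that were tested AXL fell 1.80-fold, EGFR 1.36-fold and MET 1.15-fold, MME rose 1.32-fold and EPAS1 rose by 0.19 on the log2 scale. The call for MET was lost with quantile normalization. Adjusted over the list alone the counts were also 3 lower and 2 higher, and the list was not called (median -0.21, camera adjusted p = 0.27). The median depended on the filter and the scaling, with 0.17 at a minimum mean of 0.1 CPM, -0.01 without a filter, -0.10 at a minimum mean of 5 CPM, -0.11 with total-count scaling and -0.08 with quantile normalization. A set of 14 genes of stratified epithelium, added after the first look at the data, had a median of 61.6 CPM of total counts in the control libraries and 87.9 in the knockdown libraries. The control median lay in a gap between DSG3 (23.6 CPM) and TRIM29 (99.5 CPM). The knockdown median lay between KRT15 (26.7 CPM) and TRIM29 (149 CPM), so its higher value reflects mainly TRIM29. The members went both ways. The keratin KRT6A had 420 ± 23.0 and 269 ± 16.2 CPM, COL17A1 465 ± 12.3 and 410 ± 3.49 CPM, S100A2 1049 ± 40.9 and 866 ± 72.8 CPM, PERP 643 ± 17.5 and 709 ± 36.5 CPM, and TRIM29 99.5 ± 2.92 and 149 ± 1.49 CPM, in that order and also of total counts.

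**Figure D3:**
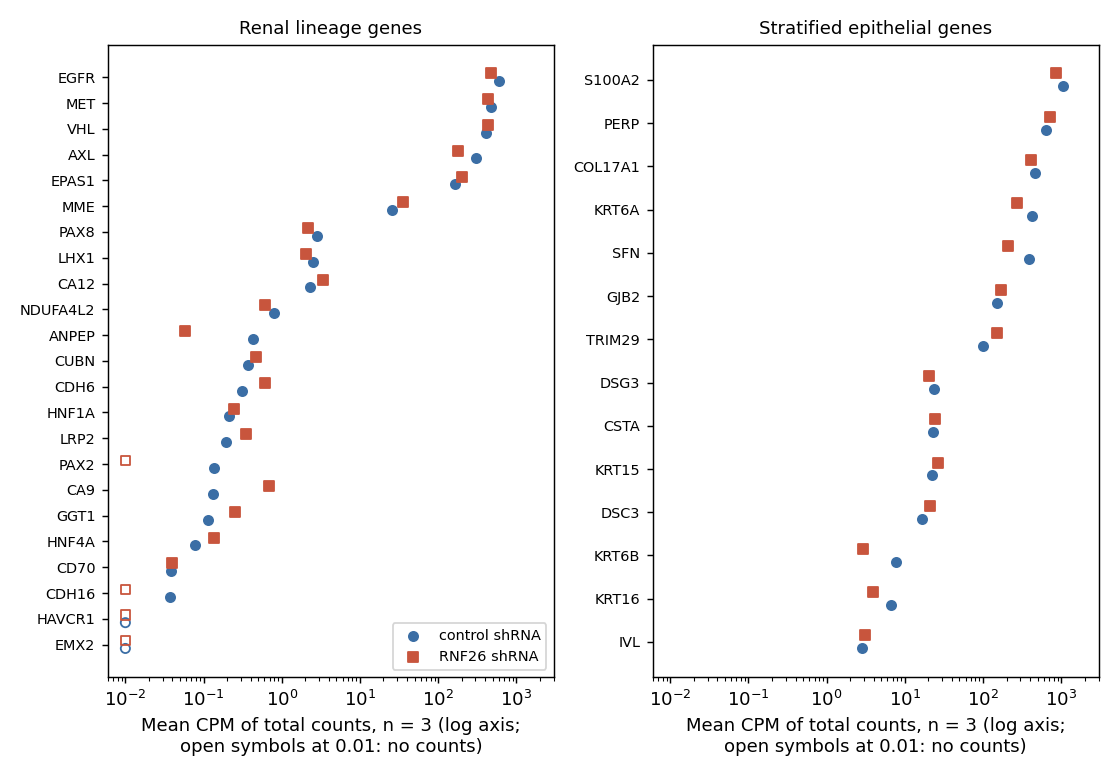
Mean CPM of total counts (log axis, n = 3 libraries per group) of renal lineage genes and 14 stratified epithelial genes, with circles for control shRNA, squares for RNF26 shRNA and open symbols for genes without counts. Most of the renal genes drawn lie below 1 CPM as a mean of all libraries, and 11 of the stratified epithelial genes reach at least 10 CPM in the control libraries.

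Few markers of endothelial cells, fibroblasts and leukocytes reached the level tested, while most of the neural markers did. Of 12 endothelial markers 2 were tested, and EGFL7 and PECAM1 did not pass (log2 fold change -0.20 and 0.18). Of 10 fibroblast markers 2 were tested, of which the collagen gene COL1A1 rose 1.42-fold, from 59.5 ± 5.19 to 84.7 ± 3.30 CPM, and THY1 did not pass (-0.15), and COL1A2 and COL3A1 had 3 and 0 counts over all libraries. Of 14 leukocyte and erythroid markers only CD14 was tested (-0.10, not passing). Of 10 neural markers 6 were tested, and the 2 above 10 CPM, MBP and GAD1, passed with log2 fold changes of -0.27 and 0.35, with the same counts adjusted over the list alone, and the list was not called (median -0.18, and -0.09 with total-count scaling, camera adjusted p = 0.50). The call for GAD1 was lost without control replicate 2 (0.25), knockdown replicate 1 (0.32) or knockdown replicate 2 (0.30). All 13 mitochondrially encoded mRNAs were listed at 0 in every library, so they could not be compared. The stratified epithelial genes named above and genes named because a count was small, beyond the rule fixed in advance, were chosen after their values were seen.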

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

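DESeq2, filterByExpr, limma on log2(CPM + 1) and the removal of a length and GC trend were tests chosen after seeing the data, and the others were planned. RNF26 was called lower under each alternative that tested single genes (all but the estimated correlation and the length and GC trend), with log2 fold changes from -4.86 to -4.70. The count of changed genes ran from 4931 (DESeq2) to 6718 (total-count scaling) with all 6 libraries, against 6117. The split between higher and lower genes moved with the scaling, from 54.5% lower to 33.8% with total-count scaling (2269 of 6718) and 44.6% with quantile normalization, where the median of all genes moved from 0.0079 to 0.099 and 0.041.

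Genes changed at least 2-fold numbered 434, and 815 with no filter, 782 with a mean of at least 0.1 CPM and 224 with a mean of at least 5 CPM, settings that by construction add or remove genes of low count. Limma on log2(CPM + 1) gave 277, and 269 without a trend, where the offset shrinks the fold of low genes. With an estimated correlation 7 lists were called in place of 18. Leaving out each library in turn gave 4959 to 5826 changed genes, 440 to 471 at least 2-fold, 17 to 19 lists and -4.86 to -4.83 for RNF26.

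Samples with the same replicate number did not deviate together (correlations 0.011, -0.027 and 0.093), so the numbers were not taken to pair the samples. With the replicate block there were 6414 changed genes, 432 at least 2-fold, 18 lists and -4.84 for RNF26, and 0 calls among named genes and lists changed. Over 139 named genes, 2831 of 2890 values kept their direction and side of the threshold, 58 lost a call and 1 gained a call (EGFL7). Over 30 lists, 624 of 659 kept both, 22 lost a call and 13 gained a call, and none of these values reversed a called direction of the test. With the robust edgeR fit and limma with a trend on log2(CPM + 1), camera ran on the main test's values, so those list calls could not differ. Depth limits what a count of 0 can show, to 0.166 to 0.180 CPM per library.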

Other observations

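The tests of overlapping reads and of S phase, the gene families and the abundant genes below were chosen after results were seen. Among genes with a mean of at least 300 CPM, 21 changed at least 2-fold, 20 lower (RNF26 included) and 1 higher, and those named in this paragraph were chosen after their values were seen. LAMB3, which encodes a subunit of laminin-332 in epithelial basement membranes, fell from 1993 ± 78.3 to 530 ± 10.9 CPM (mean ± SD, n = 3 per group). LAMA3, another subunit gene that fell by just under 2-fold, went from 1115 ± 26.4 to 570 ± 5.08 CPM. The long non-coding RNA NEAT1 fell from 1298 ± 48.7 to 361 ± 22.4 CPM, PPP1R15A, which encodes a regulatory subunit of the phosphatase that acts on eIF2 alpha, from 567 ± 15.0 to 84.6 ± 4.48 CPM, and the AP-1 gene FOSL1 from 708 ± 8.21 to 162 ± 1.30 CPM. Also in this set were the cytokine genes IL1A (log2 fold change -1.21, SE 0.041) and INHBA (825 ± 13.5 to 322 ± 8.37 CPM) and the protease gene PLAU (712 ± 3.79 to 306 ± 4.34 CPM). The atypical cadherin gene FAT2 was the one that rose, from 186 ± 3.52 to 423 ± 8.99 CPM, and at lower levels SOX2 rose 2.29-fold to 113 ± 3.92 CPM.

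Grouping tested genes by the letters of their symbol before the first digit gave 232 families of at least 8 genes. Camera with the preset correlation called 10 of them, 9 lower and 1 higher, and 0 with an estimated correlation, where the adjusted p was 0.73 for each of the families named here. Of 8 CXCL genes 7 fell, of 19 DUSP genes 10 fell, of 14 KLF genes 8 fell, and none of these rose, while of 29 KIF genes 13 rose and 4 fell.

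The groups of 3 allow 10 splits of the 6 libraries, too few for a share below 0.05. The real split called 6117 genes, 434 genes of at least 2-fold and 18 lists, and the other splits at most 1, 1 and 12. Of the 10 splits 1, the real one, reached each of these counts. Each other split mixed libraries of both groups, so any group difference entered the spread within its sides. Low gene counts there follow from such a difference, so they do not measure what chance would give. The other splits called 6 to 12 lists with the preset correlation and 0 with an estimated correlation, against 7 in the real split. Because the groups were mixed in them, neither number gives a rate of false list calls.

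RNF26 stood at 1972 CPM in the control libraries, among the 16 most abundant genes. A difference between the groups in copy number or read-through, spread over the locus, would put the median log2 fold change of neighbours at or below -1. Of 8 listed neighbours 3 were tested, CBL, MCAM and THY1, with a median of -0.17. That value argues against such a difference. It cannot address a gain present in both groups or one confined to RNF26. Reads of an overlapping gene that the shRNA does not target are argued against as the source of most of the level, since 3.48% of it remained in the knockdown libraries, when such reads would have stayed. It remains open, as hypotheses, whether the control cells may have carried an introduced RNF26 copy or expressed the chromosomal gene at this level. No biological explanation was tested for the level itself, since it needs cells without any vector, which were not analysed here.

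Renal lineage genes were low in both groups while several genes of stratified epithelium were abundant. A candidate explanation, raised after a first look at the same data, is RNA of another, stratified epithelial cell type. The 14 genes and a level of 10 CPM were set after that look but before the levels of these genes were seen. Their median was 61.6 CPM of total counts in the control libraries, above that level. PERP, SFN and GJB2 are also expressed by other epithelia, whereas KRT6A (420 CPM of total counts) and COL17A1 (465) are more restricted. Of the 14 genes 11 reached 10 CPM in the control libraries, but the median lay in a gap between DSG3 (23.6) and TRIM29 (99.5). Other members were lower, such as IVL (2.87), KRT16 (6.73), KRT6B (7.76), DSC3 (16.8) and KRT15 (22.2). CPM is a share of each library's counts, so RNA of other cells mixed into the culture would lower the renal genes in proportion. Mixing with other cells, a different cell source, drift of the line in culture and expression of these genes by A498 itself stay open. No biological explanation was tested, since the pattern is in both groups.

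Immediate early genes and replication-dependent histone genes fell together, by medians of -1.49 and -1.44. Transcript length and GC content as the whole cause are argued against, since the medians stayed at -1.47 and -1.40 after a trend on both was removed, and total-count scaling left -1.39 and -1.35. The G1/S list did not fall as a set, with a median of -0.000913, but its members went both ways, 11 higher and 10 lower. By a rule on such members, added after the values were seen, the list was taken as undecided. Fewer cells in S phase therefore cannot be told apart as a cause of the histone part. Lower recovery of RNAs without a poly(A) tail cannot be told apart for the histone genes either, since 2 of 30 listed RNAs of that kind were tested, with a median of -0.48. A difference in handling before harvest, an effect of the shRNA sequence apart from RNF26 and an effect of RNF26 loss, which the design names, could each account for the immediate early part and stay open, because all 3 go with the groups. The same 3 go with the groups for every other change given above, beyond that of RNF26 itself. An introduced RNF26 copy in the control cells alone, left open above, would go with the groups as well. Without cells free of any vector, a fall in the knockdown libraries cannot be told from a rise in the control libraries. None of those changes can be assigned to RNF26 loss alone.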
